A study of Mus musculus with 6 samples.

How the data were processed

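Small RNA libraries were made from heart cardiomyocytes of C57BL/6 mice, per the labels. Total RNA was extracted with TRIZOL and treated with DNase, and libraries were built with the NEXTFLEX Small RNA kit of Bioo Scientific. The 6 libraries fall into 4 groups by stage and genotype: 2 adult wild-type, 2 adult knockout, 1 e13.5 wild-type and 1 e13.5 knockout library. The authors deposited 1 table of whole-number read counts per miRNA, not normalised, with 1 column per library and replicates not pooled. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the trimming of adapters and random bases, the allowance for mismatches and the treatment of reads that fit several miRNAs are not given in the sources used here. No molecular identifiers are stated, so counting intervals treat reads as independent and cover counting error only.

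The deposited count table held 3208 features, of which 1234 were hairpins and 1974 mature miRNAs. A hairpin's count was close to the sum of its arms, with a median difference of 0.0098% over 178 single-copy hairpins with at least 1000 counts and 2 arms, so a read stands in both kinds of feature. Mature counts were used throughout. Mature miRNAs whose counts agreed within 1% of their total, with a total of at least 20 and counts in at least 3 libraries, were taken to hold the same reads, and 22 were merged into another, which left 1952. The choice of mature counts and the merging were made after the table was seen, and hairpin counts and unmerged counts were run as alternatives. Families with near-identical members, such as let-7, miR-15/16, miR-30 and the Sfmbt2 cluster, can share reads, so single members of these are uncertain. No feature lacked a miRNA name, and 0 columns belonged to other samples.

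Depth limits what could be seen. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.1673 and 0.1786 CPM in the adult wild-type libraries, 0.2091 and 0.1704 CPM in the adult knockouts, 0.3354 CPM in the e13.5 wild-type library and 1.123 CPM in the e13.5 knockout library. Shares of counts carry Wilson 95% intervals. A fold against a group at 0 counts is given as a bound at 3 counts over the group, and ratios with 1 or more counts in each group carry 95% counting intervals.

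Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust off, two-sided), after TMM scaling and filterByExpr with a minimum count of 10, at a Benjamini-Hochberg adjusted p of 0.05. Adult genotypes were compared in the 4 adult libraries alone, with 2 residual degrees of freedom. Stage and genotype over both stages were tested over all 6 libraries in an additive model with 3 residual degrees of freedom. The interaction used 4 group means, so its spread comes from the adult replicates and the lone e13.5 libraries are assumed to vary like them. TMM factors were 1.178, 0.9917, 1.198 and 0.7146 for the adult wild-type and knockout libraries in the adult fit. Over all 6 libraries they were 0.9022, 0.7554, 0.9616 and 0.5674, with 1.242 for e13.5 wild type and 2.166 for e13.5 knockout. The common biological coefficient of variation was 0.537 in the adult fit and 0.613 in the additive fit. At e13.5, where each genotype has 1 library, log2 folds of TMM-scaled CPM with a prior count of 2 were described without a test over miRNAs with at least 10 counts in either library.

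There were 21 lists of miRNAs fixed before the data were examined, as were the tests, the rule for named miRNAs and the other settings tried, apart from those named below as added later. They held cardiac and skeletal muscle miRNAs, cardiac stress and hypertrophy miRNAs, the let-7, miR-15/16, miR-29, miR-30, miR-34 with miR-449, and miR-378 families, and the miR-17, Dlk1-Dio3, X-linked miR-322/503, miR-290 with miR-302, Sfmbt2 and H19/Igf2 clusters. Markers of other cell types were erythroid, leukocyte, endothelial, smooth muscle and fibroblast, neuronal, epithelial and liver miRNAs. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 17 lists in adults and 19 lists between stages, and again with an estimated correlation and with fry. At e13.5 a list's median was placed among 10000 random lists of the same size matched on mean expression. A member counts as past when adjusted over the list alone when its adjusted p within the list was under 0.05, in either direction.

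The named miRNAs were the 10 largest folds in each direction among those past the threshold with a mean CPM of at least 10, or all where fewer passed. Where fewer than 5 passed, the 5 with the smallest p in each direction were added. At e13.5 they were the 10 largest folds in each direction at a mean CPM of at least 100. The rule also took the 10 miRNAs of highest mean CPM over all libraries, and of each list the 4 most abundant members and up to 6 past the threshold. It does not say in which comparison the list members are named. They are named for all lists between stages, and in adults for the cardiac and X-linked lists alone. That narrowing was chosen after a first run, in which the adult folds of many other list members lay near 0 and changed sign between settings. Other adult list results are given as counts, medians and tests, and named adult miRNAs in the account of settings leave those members out.

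The edgeR comparisons, camera in adults and the arm ratio with stage were tested on simulated counts drawn from the means and library sizes of these data. The other steps had no such test. In the adult comparison, run on 505 miRNAs, 10.4, 58.7, 91.7 and 100% of miRNAs changed by 1, 2, 4 and 6 on the log2 scale were recovered, and 1.58% of unchanged ones were called. Between stages, on 608 miRNAs, the shares were 7.5, 32.6, 79.5 and 91.7%, with 1.63% of unchanged ones. For genotype over both stages, on 605 miRNAs, they were 8.51, 28.3, 81 and 95.2%, with 0.467%. For the interaction, on 698 miRNAs, they were 0, 2.22, 23.4 and 65.2%, with 0.196%. In the adult comparison, camera called a list of 12 members moved by 2 in 20 of 20 simulations and 0 of 180 unmoved lists. The test of arm ratios, run on 168 hairpins, called 20 of 40 hairpins changed by 4 on the log2 scale and 0 of 128 unchanged ones.

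Other settings fixed with them were median-of-ratios, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-trend, other filters, an adjusted p of 0.1, other models, a replicate block, and leaving out each replicate in turn. The latter can leave 1 library in a group, which is then assumed to vary like the others. Alternatives added after the data were seen were hairpin counts, unmerged counts, erythroid miRNAs and miR-486 left out, and correlations without miR-322, miR-351 and miR-503. Correlations of folds were compared with 100 simulated sets of unchanged groups. Hairpin positions in mm10 were matched by symbol, with 1222 of 1234 hairpins given 1 position and 1181 a sequence. The long RNA lncSync was not analysed here, since the labels do not tie it to an annotated gene.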

Results

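MicroRNAs (miRNAs) were counted in heart cardiomyocytes of C57BL/6 mice lacking the long non-coding RNA lncSync and of wild-type mice, as embryos (e13.5, a stage counted in days after conception) and as adults. The series held 6 small RNA libraries. Adults were represented by 2 knockout and 2 wild-type libraries, and e13.5 by 1 library of each genotype. Mature miRNA counts totalled 17933518 and 16794840 in the adult wild-type libraries and 14347091 and 17608586 in the adult knockout libraries. The e13.5 wild-type library held 8944552 counts and the e13.5 knockout library 2671957, so rare miRNAs were measured least precisely in that library. At least 1 count was found for 1231 of 1952 mature miRNAs. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Counting intervals and floors cover counting error only. The targeted long RNA is not measured by a miRNA table, so the counts give no direct check of the genotype labels.

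Muscle miRNAs dominated the adult libraries. The cardiac and skeletal muscle list (miR-1a, miR-133a, miR-133b, miR-206, miR-208a, miR-208b and miR-499) held 32.5% ± 1.24 (SD, n = 2) of counts in adult wild-type and 33.9% ± 8.03 (SD, n = 2) in adult knockout libraries. At e13.5 it held 14.6% in the wild-type library (Wilson 95% interval 14.59 to 14.64) and 9.86% in the knockout library (9.825 to 9.897). A fixed set of 10 miRNAs, ranked by mean CPM over all 6 libraries and so not the 10 highest of each library, took 62.6% ± 2.42 (SD, n = 2) of counts in adult wild-type, 64.1% ± 8.70 (SD, n = 2) in adult knockout, 75.1% (75.07 to 75.13) in e13.5 wild-type and 64.0% (63.90 to 64.01) in e13.5 knockout libraries. The smooth-muscle miRNA miR-143-3p was the most abundant species at e13.5, at 34.97% of counts in the wild-type and 21.1% in the knockout library. In adults it held 8.81% ± 3.16 (SD, n = 2) in wild-type and 8.58% ± 1.06 (SD, n = 2) in knockout libraries. These shares were described without a test.

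The first question was which miRNAs differ between lncSync-null and wild-type adult cardiomyocytes. Products of 3 neighbouring hairpins on the X chromosome, miR-322, miR-503 and miR-351, were nearly or wholly lost from the knockout libraries. miR-322-3p fell from 265 CPM (counts scaled to an equal mature total per library) over the wild-type libraries to 0 counts in both knockouts, at least 2820-fold lower against a floor of 3 counts over the group. miR-351-5p was at least 1960-fold lower and miR-503-3p at least 179-fold lower by the same floor. miR-503-5p kept 7 counts, all in knockout replicate 1, and its CPM was 276 times higher in wild-type libraries (95% counting interval 134 to 688). The 5p arm of miR-322, the mouse counterpart of human miR-424, shares its seed with the miR-15/16 family, which represses cell-cycle genes.

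These 4 miRNAs were the only ones past the threshold among 544 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The fitted log2 folds were −14.99 (SE 0.96, adjusted p = 0.000908) for miR-322-3p, −14.47 (SE 0.94, adjusted p = 0.000908) for miR-351-5p, −11.03 (SE 1.06, adjusted p = 0.00632) for miR-503-3p and −7.91 (SE 1.02, adjusted p = 0.0128) for miR-503-5p. Folds of miRNAs at 0 counts depend on the prior count, and the floors above are the bounds. All 4 were lower in 2 of 2 knockout libraries. No miRNA passed on the higher side in the filtered fits of the 4 libraries by edgeR, DESeq2 or limma, and DESeq2 called 4 lower and limma 5. Without a filter on low counts edgeR called 9, of which 3 were higher. The other abundant arm, miR-322-5p, went from 308 CPM to 1.47 CPM, a ratio of 210 (158 to 286), with 47 counts in knockout replicate 1 and 0 in replicate 2. Its adjusted p was 0.0949 in the same edgeR fit (log2 fold −7.64, SE 1.41). miR-351-3p, a rare arm, was at least 8.59-fold lower and did not pass.

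The 7 hairpins of the cluster lie on the minus strand of the X chromosome, between 53047997 and 53054349 in mm10. Mir322 occupies 53054255 to 53054349, Mir503 53053984 to 53054054 and Mir351 53053255 to 53053353. The RefSeq span of the long non-coding RNA gene C430049B03Rik, 53053112 to 53057190, covers these 3 hairpins, whereas its GENCODE transcript, 53055046 to 53057190, ends upstream of them. The lincRNA Gm28730 (53051194 to 53053159) lies between Mir351 and the remaining hairpins. Mir542 (53049403 to 53049487) is 3767 bp beyond Mir351, and Mir450-2 (53048299 to 53048367), Mir450-1 (53048154 to 53048244) and Mir450b (53047997 to 53048078) follow. The labels do not say which annotated gene lncSync is.

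**Figure D1:**
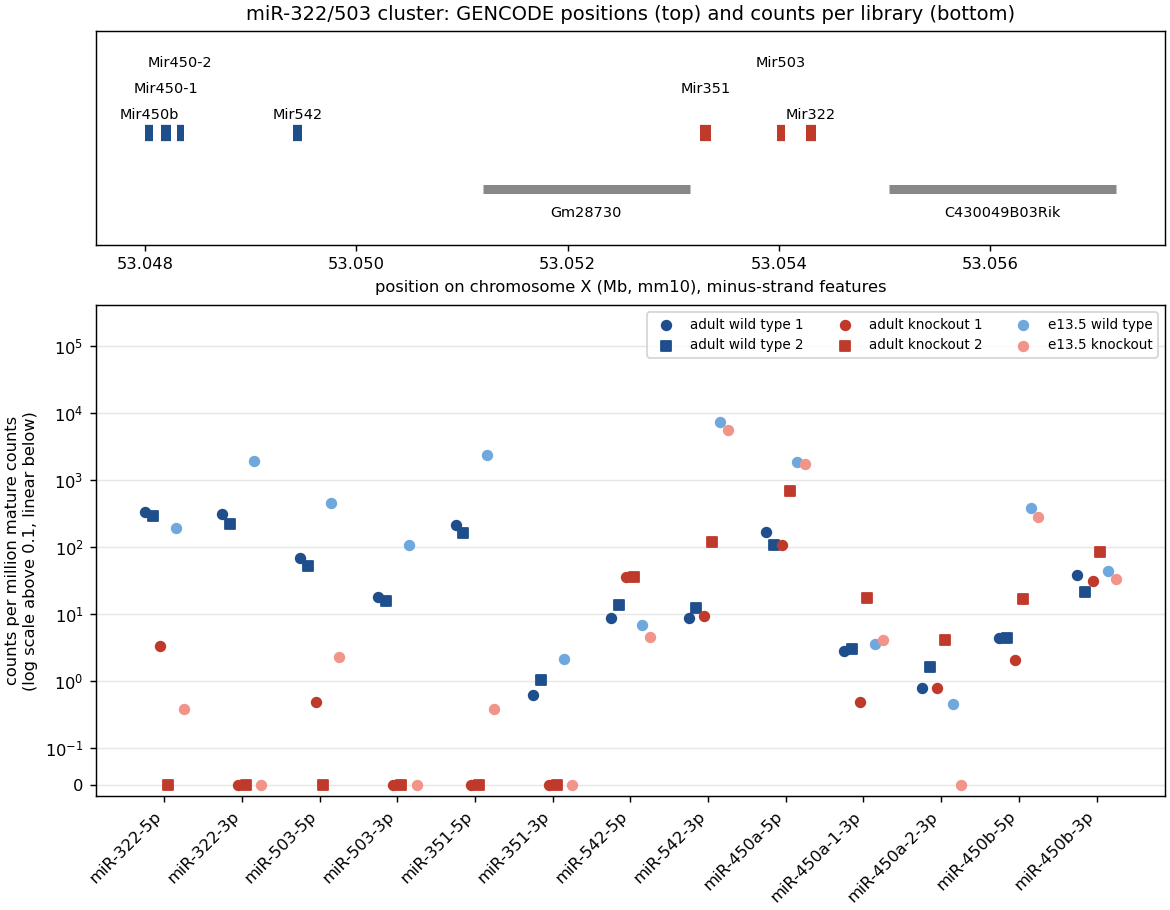
Top, GENCODE positions of the 7 hairpins (red, miR-322, miR-503 and miR-351; blue, miR-542 and miR-450) and of the long non-coding genes (grey) on the X chromosome. Bottom, CPM of the 13 arms in each of the 6 libraries, 1 point per library, on an axis that is logarithmic above 0.1 and linear below: all 3 knockout libraries read 0 for miR-322-3p and miR-503-3p, while miR-450a-5p read 137 CPM over adult wild-type and 419 CPM over adult knockout libraries.

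The distal hairpins of the cluster did not share this loss. miR-450a-5p had 137 CPM over the wild-type and 419 CPM over the knockout libraries (log2 fold 2.06, SE 0.95, edgeR adjusted p = 0.999), and miR-542-5p had 11 and 35.1 CPM (log2 fold 1.90, SE 0.55, edgeR adjusted p = 0.911). The value of miR-450a-5p rested on knockout replicate 2, with 11874 counts against 1511 in replicate 1, and without replicate 2 its log2 fold was −0.58. miR-542-3p, at 2087 counts in replicate 2 and 131 in replicate 1, went from 3.14 to −0.42. Over the 13 tested arms of the fixed X-linked list, 4 fell, none rose and 9 did not pass. When adjusted over the list alone 6 passed, a count that takes no account of direction. The list's camera test was Down (adjusted p = 8.14e-13), with adjusted p = 0.821 with an estimated correlation. The sign differed between summaries: the median log2 fold was 1.39, the mean −3.77 and the mean with absent arms at their bound −2.68.

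**Figure D2:**
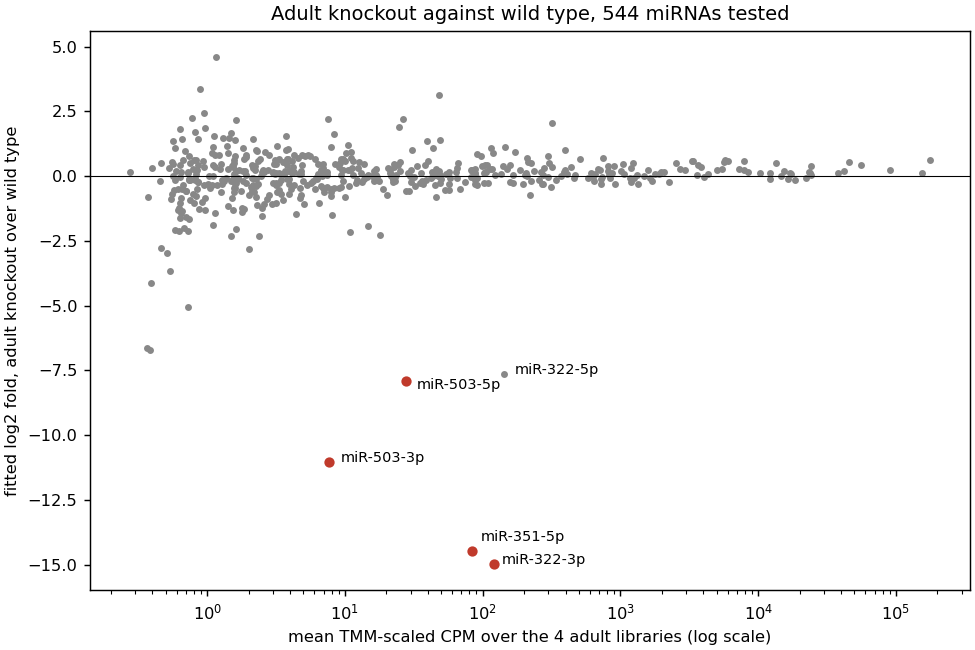
Fitted log2 fold of adult knockout over wild type (vertical axis) against the mean TMM-scaled CPM of the 4 adult libraries (horizontal axis, log scale), 1 point per miRNA tested. Red points are the 4 miRNAs past the threshold, at −7.91 and below, and miR-322-5p at −7.64 is the grey point beside them.

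The miRNAs that define cardiac muscle did not pass the test in adults. miR-1a-3p and miR-133a-3p, which act in muscle differentiation, had log2 folds of 0.63 (SE 0.71) and 0.12 (SE 0.38), and miR-133b-3p and miR-499-5p 0.10 (SE 0.40) and 0.61 (SE 0.60), each at an edgeR adjusted p of 0.999. The knockout replicates lay on opposite sides of the wild types for miR-1a-3p, at 8.15% and 25.6% of counts against 14.5% and 15.1%. Without knockout replicate 1 the miR-1a-3p log2 fold was 1.38, and without replicate 2 it was −1.09. In the cardiac list 0 of 11 members passed by edgeR, also when adjusted over the list alone (camera adjusted p = 0.565). After TMM scaling the erythroid miRNA miR-451a stood at 335 CPM in knockout replicate 1 and 63.1 in replicate 2, against 90.5 and 91.5 in the wild types.

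Among the other fixed lists with at least 3 tested members, the imprinted Dlk1-Dio3 cluster had a camera call. Its 52 tested members had a median log2 fold of −0.42, 10 were positive, and none passed the edgeR test or was past when adjusted over the list alone. The camera test was Down (adjusted p = 0.0412), with adjusted p = 0.821 with an estimated correlation. The remaining 15 lists gave camera adjusted p-values from 0.311 to 0.954, and no member passed. Apart from the X-linked arms, the smallest p-values among higher miRNAs were those of miR-217-5p, of miR-142a-5p from the leukocyte list and of miR-20a-3p from the miR-17 list, at log2 folds of 4.61, 1.35 and 1.54. Among lower miRNAs they were miR-1195, miR-7688-5p and miR-690, at −2.26, −5.06 and −2.30. None of these passed. Altogether 16 miRNAs had an unadjusted p under 0.05. The knockout replicates differed more than the wild types: over 162 abundant miRNAs the median absolute log2 difference was 0.701, with 17 at least 4-fold apart, against 0.290 and 0. Without knockout replicate 1, 35 miRNAs passed (26 higher, 9 lower), and without replicate 2, 47 (14 higher, 33 lower). The 4 calls were kept in each, but with 1 knockout library left the spread in these fits comes from the wild-type libraries alone.

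At e13.5 the same hairpins were nearly absent from the knockout library. miR-322-3p had 16789 counts in the wild-type library and 0 in the knockout, at least 1670-fold lower in CPM, and miR-503-3p was at least 96.0-fold lower. miR-351-5p had 21087 counts against 1, a ratio of 6300 (95% counting interval 1130 to 249000), and miR-503-5p 3967 against 6, a ratio of 198 (90.7 to 539). miR-322-5p had 1694 against 1, a ratio of 506 (90.7 to 20000). By contrast, miR-450a-5p had a wild-type to knockout CPM ratio of 1.05 (1.01 to 1.08) and miR-542-3p of 1.30 (1.28 to 1.32). With 1 library per genotype these differences have no replicate check, and no p-value is given.

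Of the 565 miRNAs with at least 10 counts in either e13.5 library, 38 were at least 4-fold higher and 70 at least 4-fold lower in the knockout library after TMM scaling, with a median log2 fold of −0.60. With library totals the split was 83 higher and 30 lower with a median of 0.37, and with median-of-ratios factors 54 higher and 52 lower with a median of −0.28. Among miRNAs with a mean CPM of at least 100, the highest knockout to wild-type log2 folds were 3.53 for miR-423-3p, 3.34 for miR-486a-5p, 3.34 for miR-370-3p and 3.33 for miR-451a. miR-451a and miR-486a-5p are abundant in red blood cells. Between stages they went opposite ways: miR-486a-5p was lower at e13.5 (log2 fold −3.75, edgeR adjusted p = 0.00874), whereas miR-451a was higher. They were followed by miR-744-5p (2.98), miR-1981-5p (2.87), miR-99b-5p (2.79), miR-99b-3p (2.05), miR-501-3p (1.98) and miR-423-5p (1.85). After the X-linked arms, the lowest were miR-30b-5p (−3.07), miR-106b-5p (−2.47), miR-208b-3p (−2.45), miR-101a-3p (−2.06), miR-872-5p (−1.95), miR-101b-3p (−1.91) and miR-340-5p (−1.91). These folds depend on the scaling: miR-423-5p was at 2.84 and miR-340-5p at −0.92 with library totals, and at 2.19 and −1.57 with median-of-ratios factors.

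**Figure D3:**
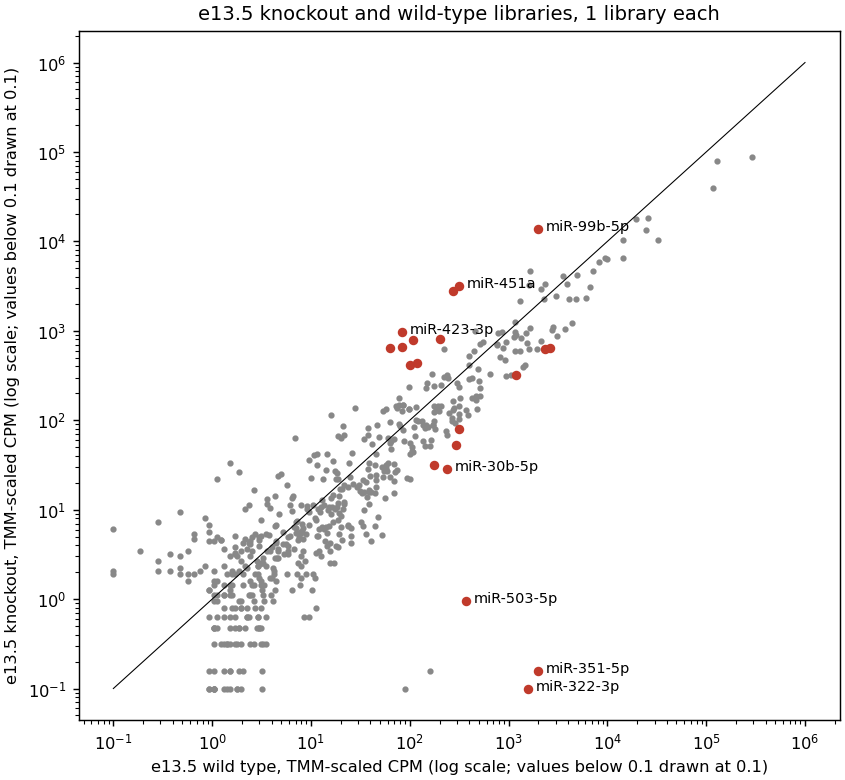
TMM-scaled CPM of the e13.5 wild-type library (horizontal axis, log scale) and knockout library (vertical axis, log scale), 1 point per miRNA with at least 10 counts in either library and values below 0.1 drawn at 0.1. Red points are the 20 named miRNAs, the line marks equal CPM, and miR-322-3p, with 0 knockout counts, lies at the lower edge.

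Set against random lists matched on mean expression, as a description of these 2 libraries, the X-linked, cardiac and Sfmbt2 lists lay lowest. The median log2 fold was −2.50 over 12 X-linked arms, with 0 positive. It was −2.17 over 10 arms of the cardiac list and −1.77 over 32 arms of the Sfmbt2 intronic cluster, and each of these 3 medians was at percentile 0 of 10000 random lists. Pluripotency clusters miR-290 and miR-302 (−1.44, percentile 1.32) and smooth-muscle and fibroblast miRNAs (−1.45, percentile 2.02) were also low. Erythroid miRNAs lay at the other end, with a median of 1.11 over 3 arms (percentile 96.2). Percentiles of the other lists ran from 6.05 for the miR-34 and miR-449 family to 77.2 for the neuronal miRNAs: 8.30 for miR-30, 13 for miR-15/16, 32.4 for leukocyte, 32.8 for miR-378, 32.9 for cardiac stress, 57.7 for Dlk1-Dio3, 60.1 for miR-17, 65.1 for epithelial, 68.3 for miR-29, 74.6 for H19/Igf2 and 75.8 for let-7.

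Averaged over stages, with 3 libraries per genotype, 5 of 679 miRNAs differed, and all 5 were lower in knockouts. They were the same 4 as in adults plus miR-322-5p, whose log2 fold was −8.10 (SE 1.27, edgeR adjusted p = 0.0189). Log2 folds of the others were −15.62 for miR-322-3p, −13.64 for miR-351-5p, −11.57 for miR-503-3p and −8.14 for miR-503-5p. No miRNA outside the cluster passed, and 14 had an unadjusted p under 0.05. Without adult wild-type replicate 1, and likewise without replicate 2, 3 calls were kept, since miR-503-3p and miR-322-5p no longer passed. With median-of-ratios factors the adjusted p of miR-322-5p was 0.0660. In the X-linked list 5 of 13 arms fell, and 6 passed in either direction when adjusted over the list alone. Its camera adjusted p was 1.55e-12 (adjusted p = 0.630 with an estimated correlation), and no other list had a camera call.

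The genotype by stage interaction asked whether the knockout difference changes between e13.5 and adults. By edgeR 0 of 769 miRNAs passed, with 46 at an unadjusted p under 0.05, against 4 by DESeq2 and 0 by limma. The 4 DESeq2 calls were miR-696, miR-423-3p, miR-744-5p and miR-99b-5p, which also had 4 of the 5 smallest edgeR p-values among positive estimates, each at an adjusted p of 0.377. The other was miR-874-3p. On the lower side the smallest p-values belonged to miR-30b-5p, miR-208a-3p, miR-135a-5p, miR-208a-5p and miR-32-3p. Spread in this test comes from the adult replicates alone. Without knockout replicate 1 the count was 87, and without replicate 2 it was 40. The edgeR fit with library totals called 1.

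The largest contrast in the series was between stages. With genotype in the model, 392 of 679 miRNAs differed between e13.5 and adult libraries, 199 higher at e13.5 and 193 lower (edgeR quasi-likelihood test). The CPM means and SDs that follow in this paragraph are TMM-scaled over all libraries. Among abundant species, miR-29a-3p had 23900 CPM ± 3240 (SD, n = 4) in adults and 35.3 ± 12.3 (SD, n = 2) at e13.5, and miR-133a-3p had 198000 ± 23200 (SD, n = 4) and 1120 ± 614 (SD, n = 2). In the other direction miR-541-5p, from the Dlk1-Dio3 cluster, went from 26.0 ± 8.07 (SD, n = 4) in adults to 3930 ± 723 (SD, n = 2) at e13.5. miR-21a-5p, one of the most abundant e13.5 miRNAs, was at 10000 ± 6480 (SD, n = 4) and 105000 ± 24300 (SD, n = 2). On library totals it had 151530 CPM in the e13.5 wild-type and 189940 CPM in the e13.5 knockout library.

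The split between higher and lower miRNAs depended on the scaling. TMM centred the log2 folds at −0.06, median-of-ratios factors at 0.72 and library totals at 0.93. The share of calls that were higher at e13.5 was 50.8% with TMM, 64.4% with median-of-ratios factors and 68.7% with library totals. The count of calls was 374 and 383 with these alternatives, of which 332 and 319 were among the 392. Without the e13.5 knockout library 261 passed and without the e13.5 wild-type library 267, and with the wild-type libraries alone 258. Stage is also confounded with any difference in dissection, cell isolation or library batch, none of which the labels give.

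Cardiac muscle miRNAs were lower at e13.5 as a list: 9 of 11 tested members were lower, 1 was higher and 1 did not pass (10 past when adjusted over the list alone, camera adjusted p = 0.00322, adjusted p = 0.344 with an estimated correlation). miR-208a-5p, from the hairpin Mir208a in an intron of Myh6, the adult cardiac myosin heavy chain gene (chromosome 14, 54949060 to 54949142, mm10), had a log2 fold of −10.06 (SE 1.04, edgeR adjusted p = 0.000133). The other arm of this hairpin, miR-208a-3p, was less reduced (log2 fold −2.62, edgeR adjusted p = 0.0345). miR-208a-5p had as few as 1 count in a library, so its fold does not stand for the hairpin. Log2 folds of miR-133b-3p, miR-133a-3p and miR-133a-5p were −8.50, −7.54 and −4.16. The exception in direction was miR-208b-3p, named after its values were seen. Its hairpin Mir208b lies in an intron of Myh7, which encodes the fetal cardiac myosin (chromosome 14, 54975700 to 54975776), and was higher at e13.5 (log2 fold 4.59, SE 1.004, edgeR adjusted p = 0.00461). miR-1a-3p did not pass (log2 fold −1.54, SE 0.75, edgeR adjusted p = 0.106), and miR-499-5p did (−1.96), although its call was lost in 8 of 18 other settings (fold −3.22 to −0.91). The ratio of miR-1a-3p to miR-133a-3p counts, which no scaling changes, was 72.7 and 64.1 at e13.5 and between 0.446 and 2.11 in adults. With library totals 5 of the 11 cardiac members were lower.

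Members of several families that accumulate in differentiated tissues were lower at e13.5. All 7 tested arms of the miR-29 family, which targets collagen transcripts, were lower (camera adjusted p = 0.000367, adjusted p = 0.213 with an estimated correlation). miR-29c-3p had a log2 fold of −9.67 and miR-29a-3p of −9.43. All 5 arms of the miR-378 family were lower (camera adjusted p = 0.00255, adjusted p = 0.344 with an estimated correlation), led by miR-378b (−7.03) and miR-378a-5p (−5.58). Of the miR-30 family 10 of 11 were lower (camera adjusted p = 0.00205, adjusted p = 0.344 with an estimated correlation), from miR-30b-5p (−5.06) to miR-30d-5p (−1.51), and 6 of 11 with library totals. Of the let-7 family, which opposes Lin28, 14 of 20 were lower and 2 higher (camera adjusted p = 0.00255, adjusted p = 0.213 with an estimated correlation). let-7d-3p had −3.66 and let-7f-5p −2.11, while let-7i-5p was higher (1.17). With library totals 8 of 20 let-7 members were lower, and the share of counts held by the let-7 family was 5.70% in the e13.5 wild-type and 8.55% in the e13.5 knockout library, against 6.35% ± 0.474 (SD, n = 2) in adult wild-type and 6.44% ± 3.33 (SD, n = 2) in adult knockout libraries. The counts adjusted over the list alone were 7 of 7, 5 of 5, 10 of 11 and 16 of 20 for these families.

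The miR-15/16 family had 6 of 11 arms lower and 1 higher (7 past when adjusted over the list alone, camera adjusted p = 0.0260, adjusted p = 0.360 with an estimated correlation), but 5 lower and 3 higher with library totals. miR-195a-5p (−8.65), miR-497a-5p (−7.94), miR-15a-5p (−6.23) and miR-16-5p (−5.79) were the lowest. Of the cardiac stress and hypertrophy list 17 of 26 were lower and 2 higher (20 past when adjusted over the list alone, camera adjusted p = 0.000417, adjusted p = 0.213 with an estimated correlation). Its lower members included miR-221-3p (−6.93), miR-34a-5p (−6.83), miR-23a-3p (−6.70), miR-27a-3p (−4.88) and miR-24-3p (−4.80). miR-21a-5p was higher (3.42). With library totals 11 of the 26 were lower and 3 higher. The list's share of counts was 15.9% and 19.6% at e13.5 in wild type and knockout, against 6.03% ± 0.202 (SD, n = 2) and 5.57% ± 0.72 (SD, n = 2) in adults. Outside the lists, miR-201-5p was at least 46.1-fold lower and miR-1249-3p had an adult to e13.5 CPM ratio of 371 (66.4 to 14600). miR-151-5p had a log2 fold of −7.73.

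Of 78 tested arms of the Dlk1-Dio3 cluster, which is imprinted, 60 were higher and 18 did not pass (61 past when adjusted over the list alone, camera adjusted p = 1.25e-15, adjusted p = 0.213 with an estimated correlation). miR-380-5p (8.50), miR-412-5p (7.32), miR-541-5p (7.32), miR-370-3p (7.14), miR-381-3p (6.92), miR-379-5p (5.54) and miR-127-3p (4.78) were among them. All 4 arms of the H19/Igf2 list were higher, 4 of 4 when adjusted over the list alone (camera adjusted p = 0.00510, adjusted p = 0.213 with an estimated correlation). miR-483-5p, from an Igf2 intron, had a log2 fold of 9.52, and miR-675-5p, from an H19 exon, was at least 205-fold higher. All 11 arms of the miR-290 and miR-302 clusters were higher, and all 11 when adjusted over the list alone (camera adjusted p = 0.000423, adjusted p = 0.267 with an estimated correlation). They remained scarce at e13.5, at 24.9 TMM-scaled CPM ± 17.4 (SD, n = 2) for miR-302b-3p. Of the Sfmbt2 intronic cluster 14 of 31 were higher and 1 lower (15 past when adjusted over the list alone, camera adjusted p = 0.00322, adjusted p = 0.344 with an estimated correlation), with miR-669c-5p at 6.23 and miR-467a-5p at 4.01. With library totals none of the 31 was lower.

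**Figure D4:**
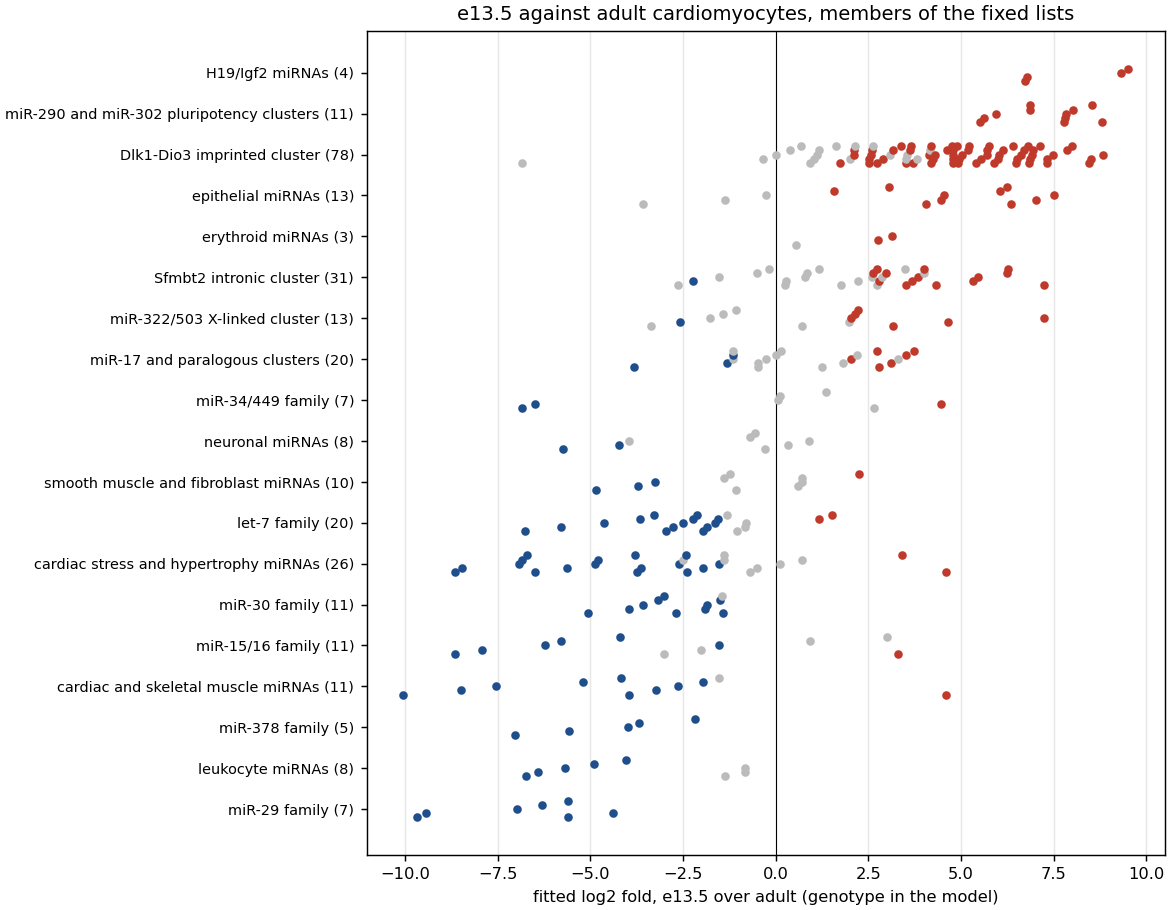
Fitted log2 fold of e13.5 over adult (horizontal axis), 1 point per tested member of each fixed list with at least 3 tested members (number in parentheses), lists ordered by their median. Red points passed the threshold and were higher at e13.5, blue points passed and were lower, and grey points did not pass; the 7 arms of the miR-29 family are all blue and the 11 arms of the miR-290 and miR-302 clusters all red.

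Lists of miRNAs typical of other cell types moved in different directions. Of the epithelial list 10 of 13 were higher at e13.5 (10 past when adjusted over the list alone, camera adjusted p = 0.00322, adjusted p = 0.267 with an estimated correlation), with miR-183-5p at 7.02, miR-200b-3p at 6.25 and miR-182-5p at 6.05. Of the leukocyte list 5 of 8 were lower and 6 past when adjusted over the list alone (camera adjusted p = 0.00322, adjusted p = 0.213 with an estimated correlation), with miR-223-3p at −6.74, miR-150-5p at −6.42 and miR-155-5p at −5.69. The erythroid miR-451a (2.76) and miR-144-3p (3.13) were higher, 2 of 3 arms in either adjustment, with a camera adjusted p of 0.267. At e13.5 miR-451a stood at 317 CPM in the wild-type and 3190 CPM in the knockout library after TMM scaling. The liver miRNA miR-122-5p was higher (5.10), at 62.4 TMM-scaled CPM ± 36.9 (SD, n = 2) at e13.5. The endothelial miR-126a-3p (−1.55) and miR-126a-5p (−2.24) were lower, 2 of 2 in either adjustment, but 0 of 2 passed with library totals or median-of-ratios factors.

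Smooth-muscle and fibroblast miRNAs had 3 of 10 arms lower and 1 higher (4 past when adjusted over the list alone, camera adjusted p = 0.321), but 2 lower and 4 higher with library totals, and 3 lower and 4 higher with median-of-ratios factors. The clustered miR-143-3p and miR-145a-5p differed: miR-145a-5p was lower (−3.26, SE 0.55) and miR-143-3p did not pass (0.60, SE 0.55). Neuronal miRNAs had 2 of 8 lower, 2 also when adjusted over the list alone (camera adjusted p = 0.320), with a median of −0.63 that turned to 0.48 with library totals. The miR-34 and miR-449 family had 1 of 7 higher, miR-34c-5p (4.47), and 2 lower, with 2 past when adjusted over the list alone, but 2 higher and 1 lower with library totals or median-of-ratios factors. Its median was 0.11, its mean −0.67 and its camera adjusted p 0.986. Of the miR-17 and paralogous clusters 6 of 20 were higher and 3 lower (7 past when adjusted over the list alone, camera adjusted p = 0.387). miR-20a-5p (3.11), miR-19b-3p (2.73) and miR-17-5p (2.02) were higher, and miR-93-5p (−1.33) and miR-25-3p (−1.15) lower, although none of the 20 was lower with library totals or median-of-ratios factors. In the X-linked cluster 6 of 13 were higher and 1 lower (6 past when adjusted over the list alone, camera adjusted p = 0.378), with miR-542-3p at 7.25 and miR-450b-5p at 4.66. The lower one was the other arm of miR-542, miR-542-5p (−2.59, edgeR adjusted p = 0.0368), and none was lower with library totals or median-of-ratios factors. Stage values of miR-351-5p (3.18) and miR-322-3p (2.21) rest on wild-type libraries, since knockouts read 0 or 1.

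Folds of the adult knockout were compared with the stage folds across 539 miRNAs, which are not independent replicates. Pearson's r was −0.183, outside the central 95% range of r, −0.0548 to 0.0673, from 100 simulated sets of unchanged groups. Spearman's rho was −0.187 and has no simulated range here. Both folds use the same adult libraries, and the knockout replicates lay further apart than the wild types (median absolute log2 difference 0.701 against 0.29). The simulated sets gave both genotypes the same spread, so r outside their range cannot tell a relation from noise shared by the folds. The covariance was −0.676 against a simulated mean of 0.00400, and 46.2% of miRNAs had the same sign. Adult and e13.5 genotype folds, which share no library, gave r = 0.405 and rho = −0.0385. Without miR-322, miR-351 and miR-503, a set chosen after the values were seen, r was −0.102. The central 95% range of r from the simulated sets was −0.0792 to 0.0911, with 0.405 above it and −0.102 below it. It was simulated over all 539 miRNAs, not the smaller set, with miRNAs varying independently. It decides nothing for −0.102 and may be too narrow for both. These are 2 relations of 1 family, and no p-value is attached to either.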

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

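The list tests of the interaction and the comparison of hairpin with arm counts were chosen after the data were seen, and no explanation is weighed for the values in this part.

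The knockout difference of 4 lists was lower at e13.5 than in adults by limma camera at the preset correlation. The cardiac and skeletal muscle list had a median interaction log2 value of −2.20 over 11 arms (camera adjusted p = 0.0011). The miR-378 family had −0.94 over 5 arms (camera adjusted p = 0.0285), the miR-15/16 family −1.15 over 12 (camera adjusted p = 0.0434) and the miR-30 family −1.06 over 12 (camera adjusted p = 0.0434). Each of the 4 had an adjusted p of 0.661 with an estimated correlation and of 0.531 by fry, and by edgeR 0 of their members passed alone or when adjusted over the list alone. Each e13.5 genotype has 1 library, so the spread behind these tests comes from the adult libraries.

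Counts outside the mature arms were read as the hairpin count minus its arms, in CPM of the mature total, over 1232 hairpins. A hairpin is listed where every knockout library of a stage had at least 100 such counts and at least 4 times the CPM of every wild-type library. In adults 0 hairpins met this, and at e13.5 it held for 17, with 1 library per genotype and no replicate check. The adult rule had to hold across replicates and the e13.5 rule did not, so 0 and 17 are not comparable. Hairpins higher in wild type were not searched. The largest was mir-6240, at 53900 CPM in the knockout and 8920 in the wild-type library. It was followed by mir-5099 (3020 and 571), mir-6236 (1290 and 145), mir-466q (1180 and 85.6) and mir-714 (1000 and 37.1). Next came mir-3470b (888 and 166), mir-3535 (816 and 55.8), mir-677 (521 and 56.5), mir-466k (250 and 38.6), mir-451a (177 and 37.9), mir-1954 (132 and 30.3) and mir-3470a (101 and 19). The lowest were mir-696 (83.8 and 1.34), mir-712 (72.6 and 0.335), mir-466i (64.4 and 13.3), mir-1194 (44.5 and 9.5) and mir-1934 (41.5 and 4.25). No group held 4 or more libraries, so single libraries were not tested against their group.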

How the results depend on the processing

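Settings with hairpin counts, unmerged counts, no erythroid miRNAs or miR-486, and no miR-322, miR-351 or miR-503 were chosen after the data were seen, and the other tests were planned. Over all settings 9 counts of main results fell and 8 rose by over 1.5 times, 10 values with no test moved and 1 changed sign. The other 80 counts or values stayed within 1.5 times or within their spread, which does not mean that no call was lost: among them counts ran from 3 to 5 in adults, from 262 to 458 between stages and from 4 to 5 over both stages. Values of named miRNAs stayed in 2372 cases, were lost in 182, gained in 79, moved in 34 and changed sign in 35. The cause was not tested for any change below except where fewer miRNAs or libraries entered. Depth limits the e13.5 knockout library most, with a floor of 1.123 CPM.

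The 4 adult calls were kept in every edgeR, DESeq2 and limma setting on mature counts except at a mean CPM of at least 10, where miR-503-3p was not among the 254 tested. Without a filter 9 miRNAs passed, 3 higher and 6 lower. Leaving out 1 library gave 5 to 47 calls, the highest without knockout replicate 2. miR-322-5p, not called in the main fit, passed in 11 of 16 other settings. Among these were the threshold of 0.1 and fits with 1 library left in a group. It had an adjusted p of 0.204 by DESeq2, and its log2 fold ran from −15.22 to −6.767 over all settings. Among other adult miRNAs, the log2 fold of miR-133a-3p was −0.066 with library totals and −0.072 to 0.20 over the left-out libraries. That of miR-133b-3p was −0.12 with library totals, −0.0007933 with 4 group means over 6 libraries, and −0.15 to 0.27 over the left-out libraries. Over the same left-out libraries miR-1a-3p ran from −1.09 to 1.38, miR-499-5p from −0.59 to 1.24, miR-450a-5p from −0.58 to 2.93 and miR-542-3p from −0.42 to 4.08, and all 4 were lowest without knockout replicate 2 and highest without replicate 1.

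With the replicate block, 5 adult miRNAs passed, since miR-322-5p had an adjusted p of 0.0122, and 2 lists were called (Dlk1-Dio3 at 0.0284, X-linked at 2.12e-12). Over both stages the blocked fit gave 5 calls. Same-numbered adult libraries did not deviate together (r = 0.00744 over 544 miRNAs), which gives no sign of a pairing but cannot exclude one. The block changed no other call.

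Between stages 239 miRNAs passed at a mean CPM of at least 10, where 332 were tested, 258 with wild-type libraries only, and 261 to 381 over left-out libraries. Of the 117 miRNAs named between stages 33 lost their call in some setting, most often miR-25-3p, miR-93-5p and miR-195a-3p (13 of 18 settings each) and let-7a-5p, miR-30d-5p and miR-126a-3p (11 of 18). At e13.5 all 17 named miRNAs outside the X-linked arms moved in 2 of 5 settings and kept their sign, such as miR-423-3p (3.52 to 4.52) and miR-30b-5p (−3.07 to −2.08). Some stage folds near 0 changed sign. miR-92a-3p was 0.29 with median-of-ratios factors, 0.58 with library totals, 0.29 by DESeq2, 0.44 at a mean CPM of at least 10, and −0.95 to 0.14 over left-out libraries. miR-128-3p was 0.09734, 0.41, 0.0973 and 0.25 under those 4 settings. miR-219a-1-3p was 0.21 with median-of-ratios factors, 0.54 with library totals, 0.20 by DESeq2, 0.58 with knockout libraries only, and −2.27 to 0.63 over left-out libraries. miR-34b-3p was −0.051 with upper-quartile factors. With knockout libraries only it was −0.62, miR-143-3p −0.35, miR-9-5p −0.085 and miR-467c-5p −0.62. Over left-out libraries these ran from −0.57 to 0.59, −0.31 to 1.37, −0.039 to 0.89 and −0.57 to 1.02.

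Over both stages hairpin counts gave 3 calls, and left-out libraries 3 to 5. The interaction had 1 call with library totals, 4 by DESeq2 and 2 without a filter, and 0 to 87 over left-out adult libraries, the highest without knockout replicate 1. At e13.5 the 108 miRNAs at least 4-fold apart became 55 with a prior count of 10, 53 at 100 or more counts in 1 library, where 318 entered, and 4 past the threshold when the adult spread was assumed. Camera with an estimated correlation called 0 lists in adults and 0 between stages, against 2 and 13 at the preset correlation, whereas fry called 0 in adults and 16 between stages, including the 13. The correlation of adult with e13.5 genotype folds was 0.711 at a mean CPM of at least 100, −0.102 without miR-322, miR-351 and miR-503, and 0.242 to 0.426 over left-out libraries. That of adult genotype with stage folds ran from −0.276 without knockout replicate 2 to −0.11. The 10 miRNAs of highest mean CPM over all 6 libraries held 75.78% in the e13.5 wild-type and 64.45% in the e13.5 knockout library over features with at least 10 counts in every library. The muscle share of the e13.5 knockout library was 9.937% without erythroid miRNAs.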

Other observations

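The tests of residual miR-322-5p counts, of arm ratios against scaling and batch, of counting error and of blood miRNAs were chosen after the result was seen, and those of low counts, GC content, depth and other splits before.

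The count ratio of the 5p to the 3p arm within a library differed with stage for 86 of 169 hairpins (50.9%, limma on log2 ratios with a pseudocount of 0.5, adjusted p under 0.05). In 11 of these the arms passed the edgeR test in opposite directions. For miR-296 the 5p arm was lower at e13.5 (log2 fold −4.73) and the 3p arm higher (7.81). miR-151 (−7.73 and 1.95) and miR-542 (−2.59 and 7.25) went the same way. The reverse held for miR-455 (5.57 and −3.60), let-7i (1.17 and −6.76), miR-342 (3.13 and −2.05), miR-744 (3.16 and −3.24) and let-7e (1.52 and −1.86). With genotype 1 hairpin passed the same limma test and 8 had an unadjusted p under 0.05. The 1 was miR-351, whose arms had 0 or 1 counts in every knockout library, so its knockout ratio is set by the pseudocount and says nothing of arm use.

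Scaling between libraries does not enter a ratio taken within a library, so by construction it leaves the ratios of these 86 hairpins as they are. Low counts predicted no such call among well covered hairpins, and 7 of the 21 with at least 100 counts of each arm in every library passed. None of the 11 hairpins with opposite arms is among those 21, but miR-151, with at least 43 counts of one arm and 6788 of the other in every library, changed by −9.72 (SE 0.84), and miR-455, with at least 31 and 51, by 9.22 (SE 0.86), whereas the size of the change of miR-296 and miR-20a, each with an arm at 0 in some library, depends on the pseudocount. The arm ratio moved the same way with stage in both genotypes for 87.6% of hairpins, but a library batch that goes with stage cannot be told apart from stage, since the labels give no batch. A change of arm use between the e13.5 and adult libraries may be involved, as an untested hypothesis. Lists typical of other cell types also differed between the stages, so these ratios cannot be assigned to cardiomyocytes alone.

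In adult knockout replicate 1, 47 counts of miR-322-5p and 7 of miR-503-5p stood beside 0 counts of miR-322-3p. Wild-type reads or cells in that library would bring 40.3 counts of miR-322-3p at the adult wild-type ratio (Poisson probability of 0 counts 3e-18) and 28.1 of miR-351-5p, and both were at 0. Reads of the miR-15/16 family counted under these names would give 54.1 counts of miR-322-5p in knockout replicate 2, which held 116214 family counts against 100930 in replicate 1, and 0 were found (Poisson probability 3.1e-24). The values argue against both sources, each under the assumption of a constant ratio. No other source and no biological explanation was tested.

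The 10 miRNAs with the highest e13.5 knockout to wild-type ratio were taken among those with a mean CPM of at least 100. Their median log2 ratio was 2.93 after TMM scaling. The lowest of their lower 95% counting limits was 1.76, which argues against counting error at the depth of these libraries. Thinning the wild-type library to the knockout depth gave medians of 3.25 to 3.61 over 100 draws, with TMM factors computed anew in each. It decides nothing, since on library totals it leaves the expected ratio of such abundant miRNAs as it was. GC content may contribute: the log2 ratio followed hairpin GC over 555 miRNAs (Spearman's rho 0.404, permutation p = 1e-05, the smallest that 100000 permutations give). Arms of a hairpin share the same GC value but were permuted as independent, so this p may be too small. It also says nothing of the spread between libraries. After the linear GC trend was removed the median was 2.35, above the bound of 2 set beforehand, yet a bootstrap interval added after that value was seen ran from 1.62 to 2.86 and leaves GC open. Blood cells could raise miR-451a and miR-486a-5p, whose knockout to wild-type ratios on library totals were 20 (19.3 to 20.7) and 20.2, whereas that of miR-144, from the transcript of miR-451a, was 2.19 (1.8 to 2.65), and after TMM scaling the log2 folds were 3.33 for miR-451a, 1.11 for miR-144-5p and −0.44 for miR-144-3p. A first criterion, miR-144 below miR-451a, was met and counted against blood, and it was replaced after the result by an upper limit below 1, since the ratio that blood gives is not known here, so blood stays open, as does genotype, with 1 library each.

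For genotype over both stages the real split gave 5 calls and the highest of the other splits 0, so 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05.

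Across 162 abundant miRNAs, which are not independent replicates, Pearson's r of log2 CPM was 0.99 between the adult wild-type libraries, 0.948 between the adult knockouts, 0.901 to 0.92 between adult genotypes and 0.83 between the e13.5 libraries. The abundant arms of miR-322, miR-351 and miR-503 were not left out. They enter each r between genotypes, at e13.5 too, so these values do not show a difference outside those arms. At e13.5 the X-linked cluster fell into parts, with a median knockout to wild-type log2 ratio of −8.97 over 6 arms of miR-322, miR-351 and miR-503 and of −1.39 over 6 arms of miR-450 and miR-542 after TMM scaling, which put the median of all miRNAs at −0.60. In CPM of library totals the wild-type to knockout ratios of the latter 6 arms ran from 0.869 for miR-450a-1-3p (0.427 to 1.91) to 1.52 for miR-542-5p (0.81 to 3.1).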
